A study of Mus musculus with 2 samples.

How the data were processed

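The series held single-cell RNA measurements of sorted small intestine epithelium from mouse embryos at embryonic day 18.5, in 1 Control library and 1 Tet3 knockout library, each a pool of cells from 2 embryos. Per the labels' protocols, cells were fixed in 90% methanol, and droplets were made with 10x Genomics 3' chemistry, in which each captured transcript is read near its 3' end and tagged with a cell barcode and a unique molecular identifier (UMI). The labels state 6000 cells used per sample and 10000 reads sequenced per cell. Tet3 is a dioxygenase that oxidises 5-methylcytosine in DNA. Per the labels, exon 5 of Tet3 was removed, which brings a premature stop codon into exon 6.

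The authors deposited 1 table of 11871 cells by 25663 genes, whose values are a linear signal scaled so that each cell sums to 10000 (called CP10K here). The submitters' processing notes name Salmon 0.14.1, alevin, Scanpy 1.6.0 and the mouse genome builds GRCm38 and mm10. The filters applied before deposition are not given in the sources used here. No cell had fewer than 1193 detected genes and none had more than 15.0% mitochondrial signal.

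Cell barcodes in the table ended in 1 of 2 suffixes, called set 0 (5933 cells) and set 1 (5938 cells) here. No label ties a suffix to the Control or the Tet3 knockout library, so neither set was given a genotype. The comparisons of Control with Tet3 knockout that were laid out before the data were examined could not be made, and the table was treated as 1 pooled sample. The contrast that these cells allowed, enterocyte-like over progenitor-like cells, took their place, with the planned gene lists, minimums and alternatives applied to it. It was chosen after the table was seen. As a check of batches, values of each set are given beside a pooled log2 ratio that they moved by over 1.5-fold, and beside shares. Most pooled CP10K levels are given without set values, and the sets differed in some of them, such as Fabp6 and Lgmn. No p-value or standard error was computed, because cells of 1 sample are not replicates.

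A cell's depth was recovered from the values themselves. The most frequent non-zero value of a cell was taken as 1 UMI, and in the median cell 94.9% of values were whole multiples of it within 0.01 (lowest cell 84.3%). The recovered total was whole within 0.01 in 96.7% of cells. Recovered totals ran from 1152 to 250630 UMIs per cell, with a median of 22381, which lies above the reads per cell that the labels state. Levels are means of CP10K over cells. Summed recovered UMIs were the alternative and carry the exact Poisson 95% intervals, while shares of cells carry exact Clopper-Pearson 95% intervals. All intervals cover counting error only. A count of 0 was read as allowing up to 3 counts.

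Clustering used Scanpy 1.11.5 with igraph 0.11.9 on both sets together without batch correction, with 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1 and seed 0. Mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes were left out. Clusters were named with marker lists taken from 13 that were fixed before the data were examined. Progenitor-like clusters had at least 9 of the 12 proliferating markers above the mean of all cells, with enterocyte markers low. Enterocyte-like clusters had a median enterocyte marker at least 2.2-fold over progenitor-like cells. Goblet-like clusters had at least 3 goblet markers at least 2-fold over all cells and 1 or more among their 10 leading genes. Clusters between these were left unnamed, as were clusters with low UMIs. So were clusters with non-epithelial leading genes, with both goblet and enteroendocrine leading genes, or with both enterocyte and proliferating markers high. Paneth markers were not part of this rule, so a goblet-like cluster could hold them. The naming rule was set, and changed more than once, after the clusters and their shares had been seen. Earlier forms gave other shares, and a 3-fold threshold in place of 2.2-fold put 58.4% of cells in the enterocyte-like class in place of 63.9%.

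Scrublet called 1 doublet in set 0 and 0 in set 1, under 0.5% of cells, and was therefore taken not to have worked. A minimum of 200 genes per cell removed 0 cells, and the stricter alternative of 1000 UMIs, 500 genes and at most 10% mitochondrial signal left out 1841. No cell was removed as a doublet, and an added alternative left out the 5% of cells with the highest score in each set. For shares of cells with a UMI, each cell was thinned to 8000 UMIs without replacement, which left out 36 shallower cells of set 0 and 51 of set 1.

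List medians were taken over members with a mean of at least 0.2 CP10K in 1 or both classes, as log2 ratios with 0.01 added to both levels. Each median was placed among 10000 random lists of the same size drawn from genes of similar mean level, and a list is said to stand above or below them past the percentiles 97.5 and 2.5. A list with fewer than 3 measured members got no median. Of the 378 symbols in the lists, 4 were not in the table, among them Ctgf and Cyr61. The genes named from each list were up to 4 members with the largest absolute log2 ratio, with Tet1, Tet2, Tet3, Epcam, Cdh1, Xist, Ddx3y and Eif2s3y always. Cell type markers were passed over in naming, a narrowing made after the first values were seen, since genes that define a class are not results. In the text, 1 gene that this list rule picked is not reported here. For set values, the rule took the 12 highest and 12 lowest genes over all cells and the 8 highest and 8 lowest in each class, from 0.5 CP10K, without mitochondrial, ribosomal protein, haemoglobin, sex-linked and predicted genes. The values named in the text are a part of these.

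The steps for ratios and list percentiles were tested on simulated data with known answers, over 5164 genes of which 200 were changed. Both simulated groups were drawn at the same depths from the mean profile of progenitor-like cells. No clustering or naming of classes was simulated, and genes were not co-regulated. The simulation therefore gives no error of the percentiles for co-regulated lists in classes chosen by expression. Of the 50 genes simulated at 2-fold, 100.0% were recovered within 0.25 on the log2 scale, and of the 48 at 0.25-fold, 85.4%. Of 400 unchanged lists, 3.25% fell outside the percentile limits. Gene positions came from the GENCODE vM21 annotation of GRCm38, which held 99.8% of the table's gene symbols. Other tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Alternatives tried were other weightings of cells, scalings, minimums, cell filters, clustering settings and doublet treatments, cells of each set alone, markers left out of the lists, and list genes left out of the clustering.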

Results

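Single-cell profiles of 11871 cells from sorted small intestine epithelium at embryonic day 18.5 were examined. The study was designed to compare 1 Control library with 1 Tet3 knockout library, to learn how loss of Tet3 bears on terminal differentiation and metabolism of the epithelium. That comparison was not analysed here, because no label says which cells came from which library. The table held 303757899 recovered UMIs, with a median of 22381 UMIs and 4411 genes per cell. Of set 1, 818 cells carried a barcode that set 0 also carried, so set 1 is given without them wherever values of the sets are compared. Pooled values and their intervals count all 11871 cells, including these 818. Set 0 had a median of 23657 UMIs per cell and set 1 without these cells (5120 cells) a median of 22374. There were no replicates of any group.

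**Figure D1:**
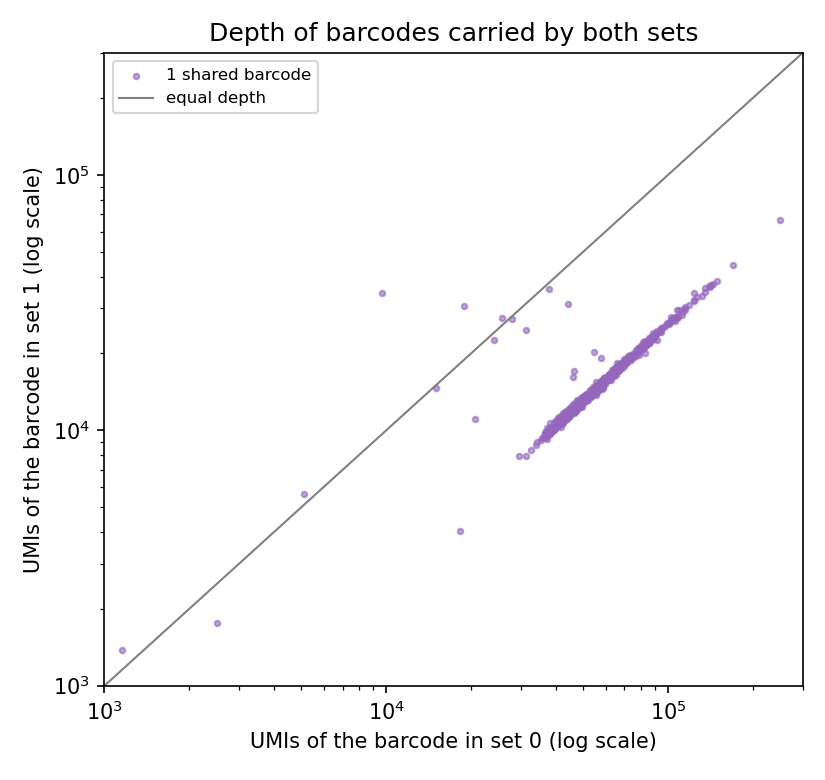
UMIs of each of the 818 barcodes carried by both sets, in set 0 (horizontal) and in set 1 (vertical), both axes on a log scale, with a line of equal depth. In 813 of the 818 pairs the cell was deeper in set 0, most of them along 1 line at a median log2 ratio of 1.93.

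Epithelial transcripts were found in nearly all cells. Epcam, an epithelial surface protein, was found in 99.9% of cells thinned to 8000 UMIs and averaged 13.1 CP10K, and Cdh1, the epithelial cadherin, averaged 0.870 CP10K. Markers of immune cells stayed at or under 0.0390 CP10K in every cluster of 20 or more cells, while a cluster of 70 cells that held enteroendocrine genes also held mesenchymal (Col3a1 at 4.08 CP10K), endothelial (Plvap at 0.483, Pecam1 at 0.222) and neural (Stmn2 at 1.32, Tubb3 at 0.885) markers, each under 0.01 CP10K in the named classes. Erythroid genes were at most 1.601 CP10K in a cluster mean (Hbb-bs). No tuft marker reached 0.1 CP10K in such a cluster, the highest being Dclk1 at 0.0701.

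Transcripts of Tet3, the gene targeted in the study, were counted at a low level in every named class, without an estimate of background RNA. The mean of Tet3 over all cells was 0.285 CP10K, and the summed level was 0.281 UMIs per 10000 (95% interval 0.276 to 0.287, from 8549 UMIs). Without the shared barcodes of set 1 the mean was 0.280 CP10K, from 8104 UMIs. Tet3 stood at 0.275 CP10K in enterocyte-like, 0.284 in progenitor-like, 0.310 in intermediate and 0.388 in goblet-like cells. Tet2, a related enzyme, averaged 0.172 CP10K, and Tet1, the third of the family, only 0.00741. Tet3 averaged 0.333 CP10K in set 0 and 0.218 in set 1. Tet3 (ENSMUSG00000034832) lies on the minus strand of chromosome 6 at 83362373 to 83459084 (GRCm38). Exon 5 of its principal transcript (ENSMUST00000186548) spans 83385985 to 83386075, while exon 12, the last of that transcript, spans 83368042 to 83369825. The labels' own exon numbering was not checked against this transcript. The positions of the counted tags along the gene are not known here, so these levels check nothing about the deletion and assign no genotype.

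Most cells belonged to the absorptive lineage. Enterocyte-like and intermediate cells together made up 80.1% of cells (95% interval 79.4 to 80.8), progenitor-like cells 17.3% (16.7 to 18.02) and goblet-like cells, the mucus-secreting lineage, 1.94% (1.70 to 2.202). Without the shared barcodes of set 1, with the clusters kept, these shares were 80.2%, 17.5% and 1.68%. Within the absorptive part, 63.9% of all cells were enterocyte-like and 16.2% lay between the enterocyte-like and progenitor-like classes and stayed unnamed. Progenitor-like clusters were led by cell cycle genes such as Top2a and Birc5 or by Olfm4, an intestinal stem cell gene, and enterocyte-like clusters by genes including Fabp6, Afp and Reg1. The goblet-like cluster was led by Spink4, Agr2 and Fcgbp, with Defa24 and Defa17, which encode Paneth cell defensins, also among its leading genes. A cluster of 70 cells held both hormone genes (Chgb, Cck and Nts) and mesenchymal genes, and 7 cells of low UMI number (median 1764) formed another. The enterocyte-like share depended on the clustering and the naming threshold and ranged from 58.4% to 83.5%. Only the 3-fold threshold gave a share below 63.9%. Leaving out the 1 cell that Scrublet called as a doublet gave 81.4%, so the boundary of this class was not stable. In that setting no cluster was intermediate, nor with 5% of doublet scores left out or with more variable genes. Values given for intermediate cells therefore depend on the clustering used here. The progenitor-like share fell to 10.3% at a lower clustering resolution.

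**Figure D2:**
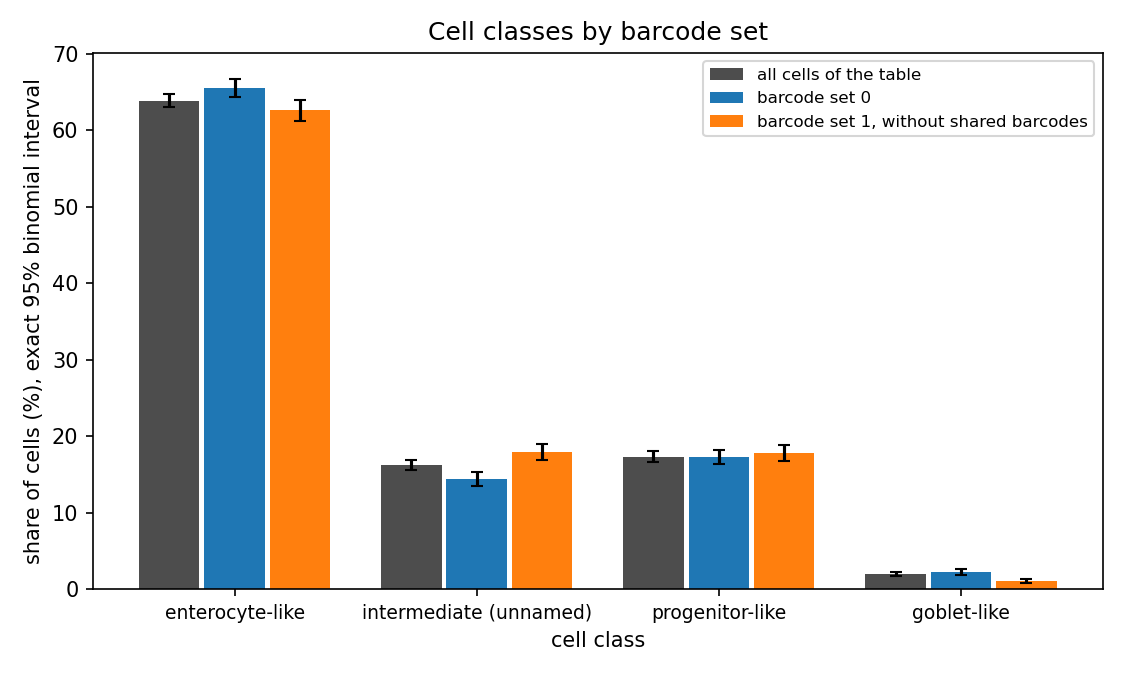
Share of cells in each class, in percent with exact 95% binomial intervals, for all cells, for set 0 and for set 1 without the barcodes it shared with set 0. Enterocyte-like cells made up 65.6% of set 0 and 62.6% of set 1, and progenitor-like cells 17.3% and 17.8%.

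Among the named classes, the sets differed most, in proportion, in the share of goblet-like cells. Enterocyte-like cells made up 65.6% of set 0 (64.3 to 66.8) and 62.6% of set 1 (61.3 to 63.9), and progenitor-like cells 17.3% (16.3 to 18.2) and 17.8% (16.7 to 18.8). The direction for enterocyte-like cells turned in 3 other settings, with 72.2% of set 0 and 73.9% of set 1 when shared barcodes were left out of the clustering, 74.03% and 74.4% at Leiden resolution 2, and 56.4% and 62.4% at a 3-fold naming threshold. The intermediate clusters, which the naming threshold kept out of the enterocyte-like class, held 14.4% of set 0 and 17.9% of set 1. Goblet-like cells made up 2.26% of set 0 (1.90 to 2.67) and 1.02% of set 1 (0.759 to 1.33), with median depths of 27182 and 10980 UMIs. Different clusters made up the enterocyte-like class in each set: clusters 3, 5, 6, 7, 9 and 11 were mostly of set 0 and clusters 10, 15, 16 and 17 mostly of set 1, so single clusters of this class were not read as cell types.

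**Figure D3:**
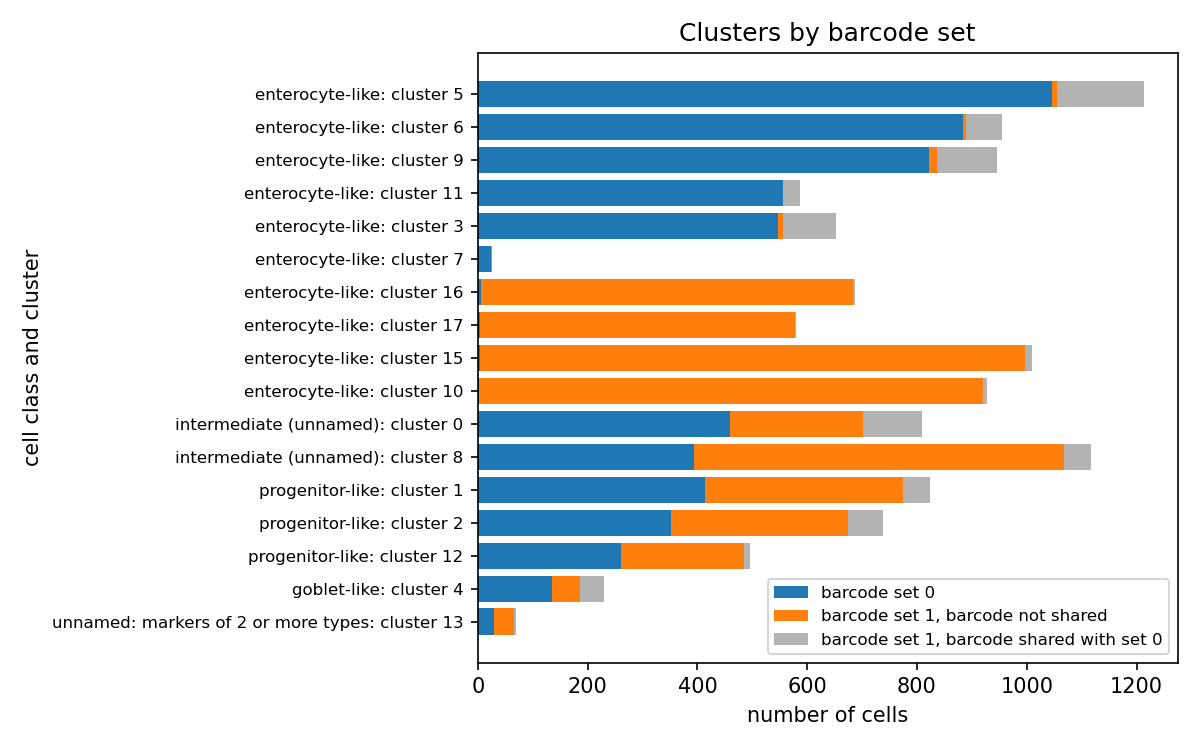
Number of cells per cluster, grouped by class and coloured by barcode set, with the cells of set 1 whose barcode set 0 also carried in grey. Enterocyte-like clusters were almost wholly of 1 set (96.0% or more of unshared cells), while the larger set held 52.0% to 53.7% of each progenitor-like cluster.

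Cells with a transcript of Mki67 or Top2a, which mark dividing cells, made up 12.3% of cells (11.7 to 12.9) after thinning to 8000 UMIs, and 18.6% without thinning. The thinned share was 56.8% in progenitor-like cells and 19.8% in goblet-like cells (17.4% in set 0 and 33.3%, 14 of 42 cells, in set 1). At Leiden resolution 2 goblet-like cells formed a cluster of 63 cells with 12 proliferating markers above the mean of all cells and a cluster of 184 cells with 0. Those clusters were named anew and are not the same set of cells as the 230 goblet-like cells used here. The thinned share was 5.37% in intermediate cells and 1.64% in enterocyte-like cells. The enterocyte-like share, from a class that should no longer divide, was taken as background (median depth 23471 UMIs, against 19819 in progenitor-like cells). Set 0 and set 1 had thinned shares of 12.0% and 12.3%. Because Mki67 and Top2a are among the markers that name the progenitor-like class, its share describes that class and is not a separate finding. Counting cells with 2 or more UMIs over the 12 proliferating markers gave 51.9%. That count also took in 37.2% of enterocyte-like and 60.8% of intermediate cells, so it does not give a share of dividing cells. It stood at 48.7% in set 0 and 55.7% in set 1.

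The absorptive program was higher in enterocyte-like than in progenitor-like cells. All 19 measured genes of lipid absorption and chylomicron assembly were higher (median log2 ratio 2.195), as were all 13 measured brush border hydrolases (2.09), all 15 brush border structural genes (1.59) and all 13 measured nutrient transporters (1.75), each at percentile 100 of random lists. The hydrolase and transporter lists named 17 genes each. Among the hydrolases under the minimum was Sis, at 0.000138 CP10K in enterocyte-like cells. Of the 13 measured hydrolases, 12 were higher in both sets. The fatty acid carrier Cd36 stood at 0.650 against 0.0460 CP10K (log2 3.56), Apoc2, an apolipoprotein, at 24.4 against 3.14 (2.96), and Dgat2, which makes triglycerides, at 8.19 against 1.23 (2.73). Among the hydrolases, Ace had a log2 ratio of 3.75 and Mme, the peptidase neprilysin, 3.33. Enterocyte-like clusters with 1818 cells lay below the progenitor-like mean of Mme. Pdzk1, a scaffold protein of the brush border (3.36), the glucose transporter Slc2a2 (3.64) and the peptide transporter Slc15a1 (2.29) also stood higher. Without the 8 genes that are also cell type markers, the lipid absorption median was 1.88.

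The lysosomal program of neonatal enterocytes, which take up and digest milk protein, was higher in enterocyte-like cells as well. All 11 measured genes were higher (median log2 2.27, percentile 100). Lgmn, a lysosomal protease, stood at 2.90 against 0.271 CP10K (log2 3.37), Ctsl, another, at 6.94 against 0.777 (3.14), Fcgrt, the neonatal Fc receptor, at 21.7 against 2.56 (3.08), and the endocytic adaptor Dab2 at 2.24 against 0.274 (2.99). Lgmn ranged from 0.147 to 9.56 CP10K over the enterocyte-like clusters, and 1 of them (927 cells) lay below the progenitor-like mean. Imprinted genes were higher in 6 of 7 (median 1.79), with Meg3 at 2.65 (3.38 in set 0 and 2.34 in set 1), the cell cycle inhibitor Cdkn1c at 2.34, the growth factor Igf2 at 1.94 and H19 at 1.79. Interferon response and MHC class I genes were higher in 11 of 11 (median 1.01, percentile 99.6), with Irf7 at 2.52 and Ifit1 at 2.26. With a minimum of 1 CP10K, the interferon median was 1.01 but lay at percentile 91.4.

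Metabolic genes did not move as 1 group between the classes. Gluconeogenesis and fructose metabolism were higher in 9 of 10 genes (median log2 1.24, percentile 99.8), with the gluconeogenic enzymes Fbp1 at 3.51, G6pc at 2.98 and Pck1 at 2.94. Retinoid and xenobiotic metabolism was higher in 11 of 12 (1.22, percentile 100), with the alcohol dehydrogenase Adh1 at 2.09 and Lrat, which esterifies retinol, at 2.04. Fatty acid oxidation was higher in 16 of 17 (0.69, percentile 99.1), with the peroxisomal enzyme Ehhadh at 1.71, the mitochondrial dehydrogenase Acadl at 1.33 and the carnitine transferase Cpt1a at 1.01. Cholesterol synthesis was higher in 15 of 18 genes (0.45, percentile 98.3), with Insig1 at 1.32 and Mvk at -0.79, and all 12 mitochondrially encoded respiratory genes were higher (0.45, percentile 98.1), with mt-Co1 at 0.88. Random lists matched to the mitochondrially encoded genes had a median of -0.39, so that percentile is set against genes that were themselves mostly lower. The cholesterol list lost its place above the random lists in cells of set 0 alone (0.38, percentile 95.3) and in 3 other settings, and the mitochondrially encoded list in set 0 alone (0.41, percentile 97.3). With a minimum of 1 CP10K, fatty acid oxidation lay at percentile 96.1.

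Other parts of energy metabolism did not stand apart from random lists. The median log2 ratio was -0.22 for 12 glycolysis genes (percentile 29.2, 8 lower), with Pfkp at 0.58 and Pfkl at -0.52. It was 0.13 for 19 genes of the TCA cycle (percentile 62.3) and 0.09 for 71 nuclear-encoded respiratory genes (percentile 80.7). Single genes departed from these medians, among them Ogdh, a subunit of the oxoglutarate dehydrogenase complex, at 1.38. Amino acid metabolism and the urea cycle had a median of 0.33 (percentile 92.0) with 9 of 15 genes higher and 6 lower, and with Gpt at 2.40, Ass1 at 2.37 and Asl at 2.19. Antioxidant genes had a median of 0.37 (percentile 92.0), with the haem oxygenase Hmox1 at 2.38 and the glutathione peroxidase Gpx2 at -4.23 (-3.81 in set 0 and -6.00 in set 1).

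Genes of growth were lower in enterocyte-like cells. All 12 measured genes of nucleotide synthesis were lower (median log2 -2.99, percentile 0), with Impdh2 of guanine nucleotide synthesis at 0.0820 against 1.39 CP10K (log2 -3.92), the purine enzyme Ppat at -3.49 and thymidylate synthase Tyms at -3.18. All 14 ribosome biogenesis genes were lower (-2.35, percentile 0), with the nucleolar proteins Nop56 at -3.75, Dkc1 at -3.37 and Fbl at -3.16. Of 82 cytosolic ribosomal protein genes, 80 were lower (-1.24, percentile 0), with Rps6 at -2.10. Heat shock genes were lower in 9 of 9 (-1.85, percentile 0.03), with Hspa1a at -3.08 and Hsp90ab1 at -1.93, and immediate early genes, which cell handling is known to induce, in 11 of 13 (-1.16, percentile 0.08), with Btg2 at -2.13. With a minimum of 1 CP10K, the immediate early list lay at percentile 3.86.

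**Figure D4:**
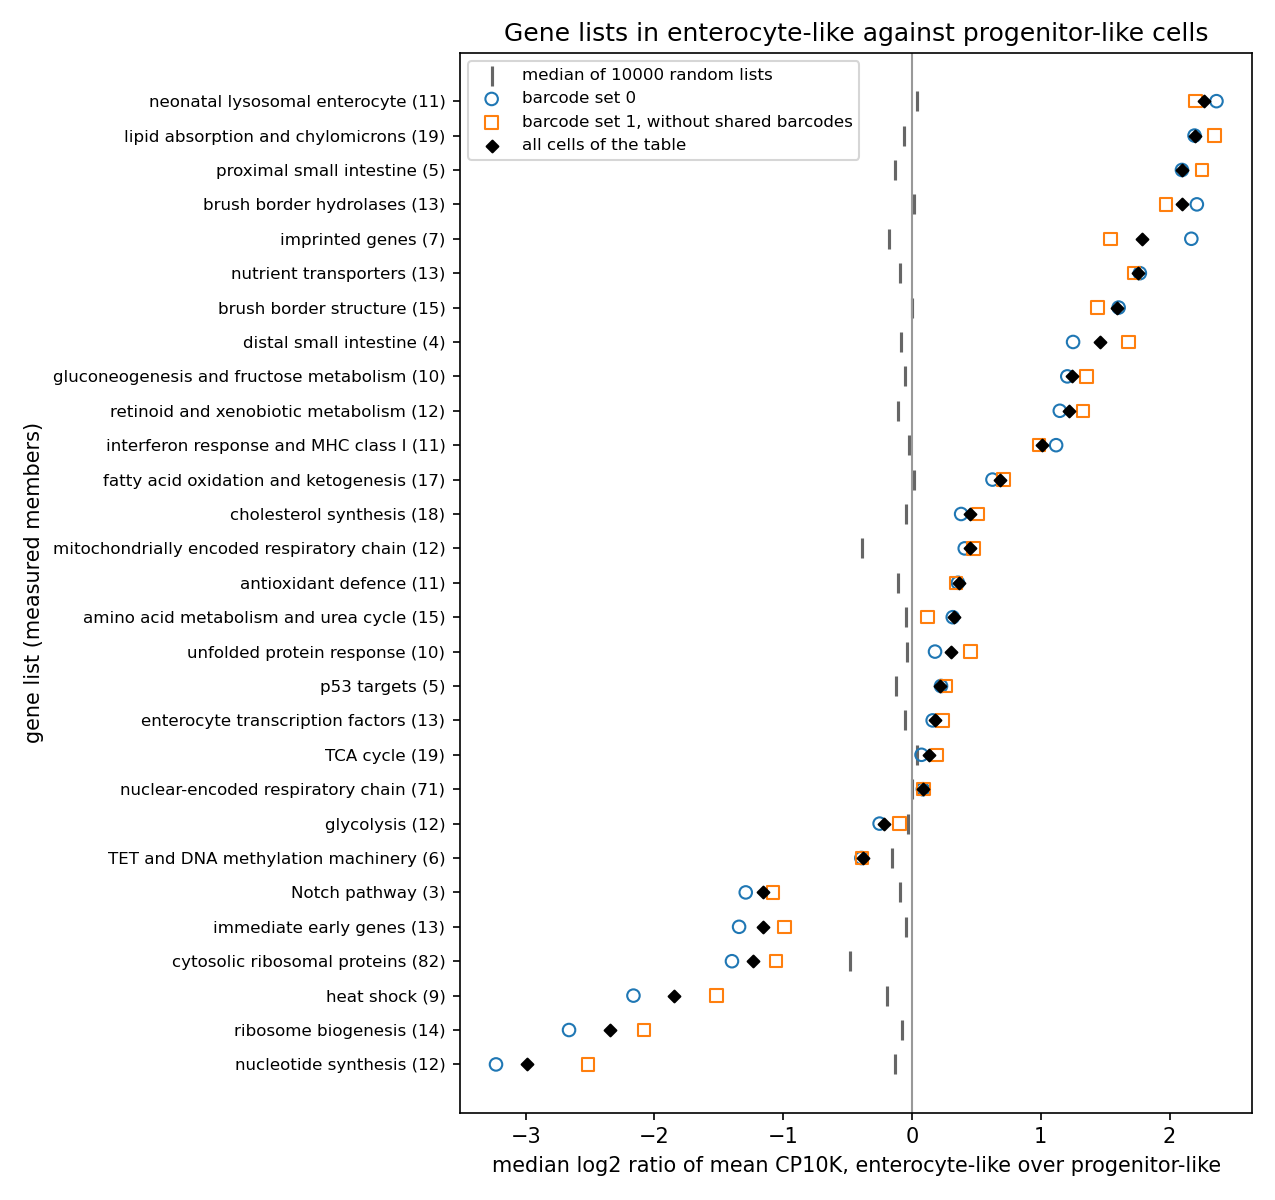
Median log2 ratio of mean CP10K, enterocyte-like over progenitor-like, for each gene list, for all cells, for set 0 and for set 1 without shared barcodes, with the median of 10000 random lists as a vertical mark. Of 29 lists, 14 stood above the random lists and 5 below, from 2.27 for lysosomal enterocyte genes to -2.99 for nucleotide synthesis.

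Regulators of the epithelium differed gene by gene. Enterocyte transcription factors had a median log2 ratio of 0.18 (percentile 76.5), with Creb3l3, a regulator of lipid genes, at 2.26, Maf at 1.76, Klf4 at 1.33 and Cdx1 at -1.07. In the TET and DNA methylation list, 5 of 6 measured genes were lower, with a median of -0.38 (percentile 35.8). The lower members included Uhrf1 (-4.49) and Dnmt1 (-2.68), which act together in maintenance of DNA methylation during replication, and the glycosylase Tdg (-0.69), and Gadd45a was higher (0.97). In the Notch list, 3 genes were measured (-1.15, percentile 7.65), with the Notch targets Hes1 at -1.15 and Nrarp at -1.12. The unfolded protein response (0.30, percentile 86.7, with Dnajb9 at 1.39 and Atf4 at -0.54) and p53 targets (0.21, percentile 70.4, with Aen at -1.53) stayed within the random lists. Of Wnt targets only 2 reached the minimum, among them Ccnd1 at -4.23, and of fetal epithelial genes 0 did, so neither list has a median.

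Regional genes were both higher in enterocyte-like cells. The distal small intestine list was higher in 4 of 4 genes (median log2 1.46, percentile 99.2), with the ileal bile acid binding protein Fabp6 at 22.5 against 2.13 CP10K (log2 3.40, with 3.71 in set 0 and 2.19 in set 1), the bile acid exporter subunits Slc51b at 1.68 and Slc51a at 1.23, and Fgf15 at 0.24 (0.09 in set 0 and 1.48 in set 1). These means came from part of the class: 5 of the 10 enterocyte-like clusters, with 4415 of 7581 cells, lay below the progenitor-like mean of Fabp6, and clusters with 5102 cells below that of Fgf15. Fabp6 averaged 37.3 CP10K in enterocyte-like cells of set 0 and 2.52 in those of set 1. The proximal list was higher in 5 of 5 (2.10, percentile 99.9). Of these, Lct and Fabp1 are enterocyte markers, and without them the median was 0.36 at percentile 77.9, with the iron exporter Slc40a1 at 2.10, Onecut2 at 0.36 and Gata4 at 0.35, where 3745 cells lay in clusters below the progenitor-like mean of Onecut2. In set 0 alone the distal list lay at percentile 97.1 (median 1.25).

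These ratios describe classes that were themselves built from expression and have no replicate check. Of 113 genes that the naming rule picked, 96 lay on the same side of the progenitor-like mean in all 10 enterocyte-like clusters. For the others, among them Mme, Klf4, Mvk and Pfkl, part of the class lay on the other side. When all list genes were left out of the clustering, 14 lists again stood above the random lists and 5 below. The clusters were still named by cell type markers, some of them list members, and cell cycle genes such as Top2a stayed in the clustering. That alternative therefore cannot show whether the lists differ apart from how the classes were built. Over the 5855 genes past the minimum the median log2 ratio was -0.09, with 2749 higher and 3106 lower. When the total left out mitochondrial, ribosomal protein and haemoglobin genes, it was -0.34, with 2478 higher and 4342 lower, and the medians of the TCA cycle (-0.08), nuclear-encoded respiratory (-0.12), amino acid (-0.01) and transcription factor (-0.03) lists fell below 0. For ratios of summed UMIs, which carry no added 0.01, the 95% half-width of the named genes was at most 0.35 (Uhrf1), with a median of 0.05. The added 0.01 draws ratios of genes at low levels towards 0: Uhrf1, at -4.49 with it, had an interval of -6.59 to -5.90 from summed UMIs. Summed UMIs also weight deep cells more, so the ratios of means can lie outside these intervals (Apoc2 at 2.96, against 2.72 to 2.76).

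Each set held cells of both sexes. In set 0, 2462 cells had Xist, the transcript of the inactive X chromosome, without a Y-linked transcript, 2447 had a Y-linked transcript (Ddx3y, Eif2s3y, Kdm5d or Uty) without Xist, 591 had both and 433 neither. In set 1 the numbers were 2159, 2231, 335 and 395. Had the transcripts been spread independently, 1563 cells of set 0 and 1250 of set 1 would have had both. Single cells of either sex would not have both, so these numbers set no bound on doublets. Cells with both may be doublets or hold background RNA, and doublets of the same sex are not seen here. Neither was estimated over all cells, and such cells were kept in the classes above. Xist averaged 2.14 CP10K over all cells, Ddx3y 0.126 and Eif2s3y 0.310.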

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

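The 3 tests of barcodes carried by both sets were chosen after the result was seen. The table held 818 barcodes that occurred in both sets of cells, above the 3 that a count of 0 allows. That bound does not measure overlap by chance, and the number that chance reuse of barcodes would give was not computed.

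The shared barcodes were concentrated in the deepest cells of set 0. All 245 cells of set 0 with 60000 or more UMIs had a partner in set 1 (100%), against 0.357% of those under 20000 UMIs, which argues against chance reuse of barcodes. In the other direction, 0.80% of set 1 cells with 60000 or more UMIs (1 of 125) had a partner, which argues against an exchange of reads in both directions. The set 1 copy held a median of 26.3% of its partner's UMIs, with a log2 depth ratio of 1.93 (5th to 95th percentile 1.88 to 1.97), and its profile correlated best with its own partner in 98.9% of pairs. Reads of set 0 cells filed under set 1 are therefore a candidate explanation, no biological explanation was tested, and values of set 1 are compared with those of set 0 without these cells.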

How the results depend on the processing

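The alternatives with 5% of doublet scores left out, without shared barcodes, with the 3-fold threshold, with list genes left out of the clustering, with markers left out and with single sets were chosen after seeing the data. No list that stood apart changed sign under any of 16 alternatives that gave it a median (nucleotide synthesis had none with a minimum of 1, where only 2 members were measured), and no named gene did under summed UMIs, which moved 71 of 113. Centring moved 79 but shifts every gene by 0.0855, too little to turn any of them. Lists that lost their place apart from random lists are named with their values above, and cholesterol synthesis also fell to percentile 96.95 with summed UMIs, 82.9 with a minimum of 1 and 92.2 at the 3-fold threshold. Lists below the random lists numbered 3 in place of 5 with a minimum of 1, which leaves 25 lists, and 6 of 30 with a minimum of 0.05 and with the total without mitochondrial, ribosomal protein and haemoglobin genes, where Wnt targets gained a median (-2.34, percentile 0.02, and -3.06, percentile 0.7). At Leiden resolution 0.5 Wnt targets lay at -3.57, percentile 3.21. Tet3 moved from 0.285 to 0.363 CP10K when the total left out mitochondrial, ribosomal protein and haemoglobin genes, a smaller total by construction, and to 0.274 in stricter cells. The proliferation share was 18.6% unthinned and 51.9% with 2 UMIs over the marker list, a count that also took in 37.2% of enterocyte-like cells. The enterocyte-like share was 74.9% at resolution 0.5, 74.1% at resolution 2, 81.3% with 4000 variable genes, 73.3% with 15 components, 77.9% in stricter cells, 81.4% without 1 Scrublet doublet, 73.8% on thinned counts, 83.5% without 5% of doublet scores, 58.4% at the 3-fold threshold, 67.3% without list genes and 73.0% without shared barcodes. With intermediate cells it was 87.2%, 83.1%, 81.3%, unmoved with 15 components, 81.2%, 81.4%, 79.3% and 83.5% in that order, then 81.9% without list genes. Progenitor-like cells were 10.3% at resolution 0.5, 12.4% at resolution 2, 15.3% with 4000 genes, 14.5% in stricter cells, 15.9% without the Scrublet doublet, 13.8% without 5% of doublet scores and 14.6% without list genes, and goblet-like cells 1.34% with 4000 genes and 1.48% with 15 components. The cause of these moves was not tested. No paired analysis was possible because no cell could be tied to a library. The alternative of epithelial-like clusters only was not run.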

Other observations

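The tests of separation by barcode set were planned before their results were seen, and the test of doublets was chosen after a first form of its result was seen. No genotype is known for either set, so the values below compare barcode sets only.

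Some clusters had leading or marker genes not yet described, given here as values of clusters and not as cell types, with genes chosen after their values were seen. Cluster 7, with 26 cells, had the enterocyte program together with interferon-induced antiviral genes: Rsad2 averaged 8.69 CP10K, Isg15 9.93 and Ifit3 8.34. Cluster 11 had Fabp6 at 125.9 CP10K, Fgf15 at 2.65 and Afp, the fetal serum protein, at 32.6, and cluster 17 had Afp at 33.2 with Fabp6 at 2.09. In cluster 13 the hormone transcripts Chgb, Cck and Nts averaged 40.9, 30.7 and 31.6 CP10K. Defa24 and Defa17 averaged 9.28 and 7.82 CP10K in the goblet-like cluster, while lysozyme Lyz1 averaged 0.0540.

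Several distal, lysosomal and metabolic genes had other levels in set 0 than in set 1. Over all cells Fabp6 averaged 27.5 CP10K in set 0 and 1.90 in set 1, Fgf15 1.10 and 0.0808, the glutathione transferase Gstp2 3.59 and 0.595, the lysosomal protease Lgmn 3.07 and 0.736, and the secreted peroxidase Gpx3 13.6 and 3.36. Ctrb1 averaged 0.170 in set 0 and 0.766 in set 1, Fkbp11 0.433 and 1.21, and the retinaldehyde dehydrogenase Aldh1a1 0.252 and 0.625. In progenitor-like cells H19 averaged 8.19 and 14.2 CP10K, and Igf2 1.34 and 2.72. In enterocyte-like cells with Xist alone Fabp6 averaged 33.8 in set 0 and 3.98 in set 1, and in those with a Y-linked transcript alone 41.6 and 1.23.

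Enterocyte-like cells separated by barcode set: 97.7% of their nearest neighbours were of the same set (3206 cells per set) and 96.3% at the number of progenitor-like cells, against 90.7% in intermediate (852 per set) and 74.6% in progenitor-like cells (909 per set) and 50% for fully mixed sets. Depth as the whole cause was argued against by thinning to 8000 UMIs, which left 96.6%. Free RNA as the whole cause was argued against by 47 genes chosen for a set difference in enterocyte-like cells. Their set difference in progenitor-like cells, divided by that in enterocyte-like cells, had a median of 0.193 (25th to 75th percentile 0.069 to 0.476), where free RNA would give about 1.19. The quotient was at or above 0.5 for 10 of the 47, and choosing genes by the divisor can lower it, so free RNA as a part was not excluded. Sampling of different gut regions was not excluded, since the test of it, on cells with Onecut2 and without Fabp6 (95.9%), selects by a gene that itself differed between the sets. It and differences between embryos, between library preparations and between genotypes may each have a part and could not be told apart here, and cells with Xist alone and with Y-linked transcripts alone also separated within a set among enterocyte-like cells, at 71.0% in set 0 and 60.1% in set 1, but hardly among progenitor-like cells, at 51.7% and 51.1%.

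At Leiden resolution 2, 157 cells without shared barcodes had cell cycle genes (Top2a at 0.917 CP10K) together with enterocyte genes (Fabp1 at 142.1 CP10K), at a median of 41599 UMIs. Both Xist and a Y-linked transcript were found in 42.7% of them (95% interval 34.8 to 50.8). Of the 114 with 35000 or more UMIs it was 44.7% (35.4 to 54.3). At that depth the share was 9.22% (5.64 to 14.0) in progenitor-like and 21.6% (19.4 to 23.9) in enterocyte-like cells. Doublets of a dividing cell and an enterocyte are a candidate explanation for these cells. Doublets of cells of the same sex would not show both transcripts, so cells without both can be doublets too. How many of these cells were doublets is therefore not known, and a transitional dividing enterocyte was not excluded.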
